A study of Mus musculus with 12 samples.

How the data were processed

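The series measured messenger RNA by sequencing in 12 libraries of primary CD8 T cells from the spleen of C57BL/6 mice. The labels place the libraries in 4 groups of 3: wild type (WT) and Trmt61A conditional knockout (cKO), each at 0 h and at 48 h. Their titles number the libraries 1 to 3 in each group, and their descriptions number the WT libraries 1, 3 and 6. Replicate numbers here are those of the titles. The labels do not say that a number marks a single mouse or that the same number at 0 h and 48 h is the same mouse. Nor do they say what was done to the cells between 0 h and 48 h. The p-values given here therefore measure the spread between these libraries, part of which may be technical.

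RNA was extracted with TRIzol and libraries were made from 3 µg of total RNA with a NEBNext Ultra RNA kit, per the labels' protocols. The tools named are fastp 0.20.1, FastQC 0.11.9, HISAT2 2.1.0, SAMtools 1.9 and HTSeq 0.11.2, with the genome build GRCm39, per the submitters' processing notes, which give no order, settings or strand option. The deposited table holds raw read counts per gene, as whole numbers, for 16352 genes in the 12 libraries, with no library left unmapped to a label. Because no strand setting is stated, a gene and an overlapping or antisense neighbour cannot be told apart in these counts. Values of genes with near-identical copies or many processed pseudogenes are uncertain in the same way, among them Hba-a1, Hbb-bs, Hspa1a, Hspa1b, the ribosomal protein genes and glycolytic genes such as Pgk1, Ldha and Tpi1.

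Genes are named by the symbols of the deposited table. Their NCBI gene numbers were matched to a GRCm38.p6 gene table for gene types, and 16245 of the 16352 matched. No coordinates are given, because that build differs from the one the counts were made with. Transcripts encoded by the mitochondrial genome, the T cell receptor and immunoglobulin constant genes, Trmt61b, Mx1, Mx2 and Xist were not analysed here, and 1 of the 37 gene lists, made of mitochondrially encoded transcripts, therefore had no member to test.

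Total counts ran from 34341847 to 40270659 per library. The median count of a tested gene was 955, and a count of 100 carries a counting error of about 10 percent. Intervals and errors given for counts cover counting and the spread between libraries, not other sources.

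Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 12404 genes tested and 3948 not tested. Libraries were scaled with TMM factors, which ran from 0.956 to 1.07. One quasi-likelihood model with a mean for each of the 4 groups was fitted to the 12 libraries, with 8 residual degrees of freedom. The 5 comparisons were drawn from it: cKO against WT at 0 h and at 48 h, 48 h against 0 h in WT and in cKO, and the interaction, which is the cKO change from 0 h to 48 h minus the WT change. A gene was called when its two-sided p, adjusted over the tested genes by the Benjamini-Hochberg method, was under 0.05, with no minimum fold. Levels are given as CPM, edgeR's counts scaled by library size, with TMM factors. Errors of log2 fold changes are standard errors, taken as the size of the log2 fold change divided by the square root of the F statistic, and errors of CPM are standard deviations over 3 libraries.

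The 37 gene lists cover sterol and lipid metabolism, translation, energy metabolism, stress responses, the cell cycle, T cell states, and markers of other cell types of the spleen. Each was tested against the other tested genes with camera from limma 3.58.1, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison. Beside it stand camera with a correlation estimated from the data, fry, which asks whether a list moves one way on balance, and the number of members called when p is adjusted over the list alone. The pathway annotations of the deposited table gave 310 further sets, tested in the same way.

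The named genes follow a rule. It takes these 16 genes in every comparison (Trmt61a, Trmt6, Acly, Hmgcs1, Sqle, Srebf2, Myc, Mki67, Gzmb, Prf1, Ifng, Tnf, Il2, Il2ra, Cd69 and Cd8a). For each comparison of 2 groups it adds the 10 called genes with the highest and the 10 with the lowest fold change, among those with a mean of at least 5 CPM over the 6 libraries and no overlap between the groups, a pattern that chance gives for 10 percent of genes in 3 against 3. For the interaction it adds up to 5 called genes in each direction with a mean of at least 5 CPM. It also takes up to 4 members of each described list, those with the smallest adjusted p. A few genes that the rule takes are not reported here. The gene lists, this rule, the tests, the threshold and the first set of alternatives below were fixed before the data were examined.

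The first set of alternatives was RLE and upper-quartile scaling, no filter on low counts, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom, a fit of the 6 libraries compared, a block for the replicate number, a block for genotype and number, and leaving out each library in turn. Leaving out both libraries of one genotype and number, and leaving out the 4 libraries of cKO replicate 1 and WT replicate 3, were chosen after seeing the data, as were the list medians under other scalings and with single libraries left out. DESeq2 was run on all 16352 genes of the deposited table with its own filter on low counts. Its numbers of calls therefore differ from those of edgeR in the genes tested as well as in the tool. Blocks are given as alternatives because the labels do not pair the libraries. Splits of the libraries into other groups were refitted, 10 for each comparison of 2 groups and 100 drawn with a fixed seed for the interaction.

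The programs were tested on simulated data, counts drawn from the means, totals and gene-wise dispersions of these libraries, for cKO against WT at 48 h over 12404 genes with 200 changed. With 3 libraries against 3, edgeR recovered 67.2 percent of genes changed 1.5-fold, 86.6 percent of those changed 2-fold and 97 percent of those changed 4-fold, and 16 of its 183 calls were false. With 2 against 3 it recovered 50.7, 85.1 and 97 percent, with 16 false of 171 calls. DESeq2 recovered 71.6, 91 and 97 percent with 35 false of 208 calls, and limma-voom 61.2, 86.6 and 97 percent with 27 false of 190. At 0 h, where no gene was changed, edgeR called 2. The list test called the raised list and 0 of 36 unchanged lists. The simulated genes were drawn independently of each other. This part therefore cannot show how often the list test errs on lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.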

Results

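The data are gene-level read counts of 12 RNA-seq libraries from spleen CD8 T cells, 3 each of WT at 0 h, cKO at 0 h, WT at 48 h and cKO at 48 h. The series title names tRNA m1A modification, cholesterol biosynthesis and antitumour immunity of CD8 T cells, and the targeted gene, Trmt61a, encodes the catalytic subunit of the enzyme that places this mark on tRNA. Total counts per library ran from 34341847 in the library labelled cKO replicate 1 at 0 h to 40270659 in WT replicate 3 at 48 h. On the first principal component of the 12 libraries, which held 81.7 percent of the variance, the 0 h libraries lay between -95.2 and -90.5 and the 48 h libraries between 81.5 and 101. Values after ± are standard errors for log2 fold changes and standard deviations for CPM, with n = 3 libraries per group unless stated.

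Trmt61a itself was low in 4 of the 6 libraries labelled cKO and at the WT level in the other 2. At 0 h its level was 27.4, 29.8 and 26.3 CPM in WT, 28.1 CPM in the library labelled cKO replicate 1, and 0.807 and 1.88 CPM in cKO replicates 2 and 3. At 48 h it was 42, 38.2 and 34.8 CPM in WT, 42.5 CPM in the library labelled cKO replicate 1, and 0.956 and 1.1 CPM in cKO replicates 2 and 3. The library labelled cKO replicate 1 thus held 101 percent of the WT mean at 0 h and 111 percent at 48 h, on counts of 939 and 1663. The shares were 2.9 and 6.76 percent at 0 h and 2.49 and 2.87 percent at 48 h in cKO replicates 2 and 3. With the groups as labelled, the log2 fold change of Trmt61a was -1.44 ± 1.14 at 0 h (edgeR adjusted p = 0.726) and -1.36 ± 1.11 at 48 h (edgeR adjusted p = 0.504). Without both libraries labelled cKO replicate 1, a choice made after seeing the data, it was -4.38 at 0 h (edgeR adjusted p = 1.54e-06) and -5.21 at 48 h (edgeR adjusted p = 2.56e-07). Trmt6, the partner subunit of the enzyme, had 48.4 ± 4.28 CPM in WT and 48.7 ± 3.25 CPM in cKO at 0 h and 100.6 ± 9.62 and 100.2 ± 5.6 CPM at 48 h, and was not called at either time. Counts also set WT replicate 3 apart. Its libraries had 0 counts of Uty, Kdm5d and Eif2s3y at both times and 2 and 0 counts of Ddx3y, whereas the other 10 libraries had at least 694 counts of each of these Y-linked genes. Each direction given below between cKO and WT keeps the groups as labelled, with the library labelled cKO replicate 1 among cKO, and the values without it are given beside the counts.

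**Figure D1:**
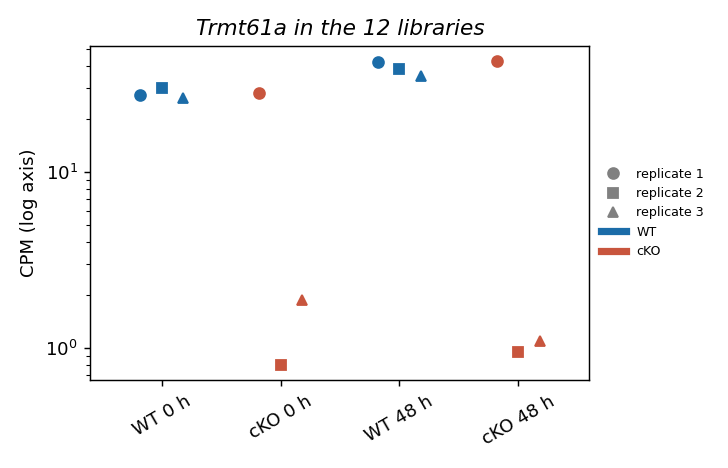
Level of Trmt61a in each of the 12 libraries, in CPM on a log axis, with 1 point per library and the groups side by side. The library labelled cKO replicate 1 lies at 28.1 CPM at 0 h and 42.5 CPM at 48 h, among the WT libraries, and cKO replicates 2 and 3 lie between 0.807 and 1.88 CPM.

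The comparison of 48 h with 0 h in WT shows what changed in unmodified cells over the 2 days. Cell cycle, activation, glycolysis and sterol synthesis genes rose and naive T cell and ribosomal protein genes fell. Gzmb, the cytotoxic protease granzyme B, went from 4.45 ± 0.748 to 3956 ± 466 CPM, Il2ra, the high-affinity subunit of the interleukin 2 receptor, from 3.45 ± 0.24 to 1102 ± 51.4 CPM, and Ifng, the cytokine interferon gamma, from 0.834 ± 0.475 to 379.7 ± 61.4 CPM. Of the 12404 genes tested, 4583 rose and 4768 fell, 2592 and 2448 of them by at least 2-fold (edgeR, adjusted p under 0.05).

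Proliferation genes rose almost without exception in WT. In the list of DNA replication and S phase genes, 50 of 50 members rose, with a median log2 fold change of 2.96, and in the G2/M and mitosis list 43 of 44 rose and 1 fell, with a median of 5.46. Mki67, a marker of cycling cells, rose by 6.16 ± 0.16, Cdc6, which licenses replication origins, by 7.16 ± 0.15, and Aurkb, a mitotic kinase, by 6.92 ± 0.13. In the T cell activation list 24 of 27 rose and 1 fell, with Icos up by 3.34 ± 0.07, Tfrc by 3.79 ± 0.077 and Tnfrsf9 by 5.57 ± 0.13. All 3 lists stood out from the other genes with a preset correlation (camera adjusted p = 1.09e-57, 8.95e-68 and 7.39e-20) and also with an estimated correlation (adjusted p = 0.00254, 3.2e-05 and 0.00254).

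Metabolic and biosynthetic lists also rose in WT. In the cholesterol biosynthesis list 19 of 20 members rose, with a median log2 fold change of 3.02, and none fell, by edgeR. Hmgcs1 went from 44.3 ± 6.47 to 635 ± 37.5 CPM and Sqle from 8.17 ± 2.7 to 225 ± 8.17 CPM. The list's camera adjusted p was 9.61e-10, and the adjusted p = 0.278 with an estimated correlation. Insig1, which holds sterol-sensing proteins in the endoplasmic reticulum, rose by 3.48 ± 0.17, while Abca1 and Abcg1, which export sterols, fell by 3.82 on the log2 scale (SE 0.23) and by 2.42 (SE 0.16). In the glycolysis list 20 of 20 rose, Tpi1 by 4.66 ± 0.11 and Hk2 by 6.86 ± 0.18, with a median of 2.5 (camera adjusted p = 4.46e-19, and adjusted p = 0.0522 with an estimated correlation). In the list of MYC targets and ribosome biogenesis genes 41 of 42 rose, among them Ncl and Odc1, with a median of 1.55 (camera adjusted p = 7.74e-18, and adjusted p = 0.189 with an estimated correlation), and Myc rose by 1.71 ± 0.13. Of the cytosolic aminoacyl-tRNA synthetases, 22 of 23 rose, with a median of 1.56 (camera adjusted p = 4.58e-08, and adjusted p = 0.0332 with an estimated correlation). The ribosomal protein genes went the other way: 76 of 79 fell and 1 rose, with a median of -0.84 (camera adjusted p = 4.89e-15, and adjusted p = 0.336 with an estimated correlation). Upper-quartile scaling moved the median gene by -0.104 in this comparison and by -0.0926 in cKO. In the integrated stress response list 22 of 27 rose and 1 fell in WT, with a median of 2.32 (camera adjusted p = 0.00114, and adjusted p = 0.512 with an estimated correlation).

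T cell identity and function genes moved both ways in WT. In the naive and memory list 24 of 30 fell and 3 rose, with S1pr1, the receptor that guides exit from lymphoid tissue, down by 3.95 on the log2 scale (SE 0.1) and Ccr9 by 5.82 (SE 0.19) (camera adjusted p = 1.22e-13, and adjusted p = 0.0117 with an estimated correlation). In the effector list 20 of 32 rose and 11 fell, with Lta up by 4.09 ± 0.1 and Prf1, the pore-forming protein perforin, falling by 1.36 on the log2 scale (SE 0.11). Il2 went from a mean of 0.0188 to 28.3 CPM. Lag3 and Ctla4, inhibitory receptors, rose by 6.54 ± 0.29 and 5.89 ± 0.3. Cd8a fell by 1.04 on the log2 scale (SE 0.061), Cd3e by 1.58 and Cd8b1 by 1.93, among 11 of 14 CD8 identity genes that fell. Zbtb32, a transcriptional repressor, went from 0.169 to 161 CPM and Lif, a cytokine, from 0.415 to 227 CPM, and Hspa1a and Hspa1b fell from 127 and 392 CPM to 0.428 and 1.84 CPM. Markers of other cells fell in the same libraries. The 16 B cell markers summed to 233 to 358 CPM at 0 h and 31.4 to 47.7 CPM at 48 h, and the 24 myeloid markers to 253 to 293 CPM and 92.8 to 102 CPM.

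The comparison of 48 h with 0 h in cKO asks the same of the libraries labelled cKO. The same main lists moved: S phase genes rose in 50 of 50 cases, G2/M genes in 43 of 44, activation genes in 24 of 27 with 1 lower, glycolysis genes in 19 of 20, and naive and memory genes fell in 24 of 30 with 3 higher. Gzmb went from 3.27 ± 0.845 to 2295 ± 429 CPM, Ifng from 0.533 ± 0.335 to 183 ± 56.9 CPM and Mki67 from 12.7 ± 3.38 to 949 ± 19 CPM. In all, 4513 genes rose and 4491 fell (edgeR, adjusted p under 0.05), and 4234 and 4124 did so without both libraries labelled cKO replicate 1. Across the 12404 genes, which are not independent replicates, the fold changes in WT and in cKO had a Pearson r of 0.924 and a Spearman rho of 0.943, and 8193 genes were called in the same direction in both.

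Sterol synthesis genes rose in cKO as well. In the cholesterol biosynthesis list 18 of 20 rose, with a median log2 fold change of 2.52 (camera adjusted p = 6.75e-08, and adjusted p = 0.338 with an estimated correlation). Hmgcs1 rose by 3.37 ± 0.18. In the integrated stress response list 23 of 27 rose and 1 fell, with a median of 2.99 (camera adjusted p = 0.000118, and adjusted p = 0.476 with an estimated correlation). Csf2, which encodes the cytokine GM-CSF, had 0 counts in the cKO libraries at 0 h and 10.6 ± 3.73 CPM at 48 h. Among the genes that fell most were Fos, an immediate early transcription factor, by 6.4 on the log2 scale (SE 0.42), Ggt1 by 5.86 (SE 0.16), and the chaperone genes Hspa1a and Hspa1b, whose 0 h levels of 336 ± 391 and 799 ± 833 CPM varied more between libraries than their means. In the type I interferon list 25 of 36 fell and 1 rose in cKO (camera adjusted p = 0.0384, and adjusted p = 0.653 with an estimated correlation), against 9 lower and 5 higher in WT. The call in cKO was lost without cKO replicate 3 at 0 h (camera adjusted p = 0.105), without the library labelled cKO replicate 1 at 48 h (camera adjusted p = 0.0598), with upper-quartile scaling (camera adjusted p = 0.0568), with a filter at 1 CPM (camera adjusted p = 0.052) and with DESeq2 (camera adjusted p = 0.0657).

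**Figure D2:**
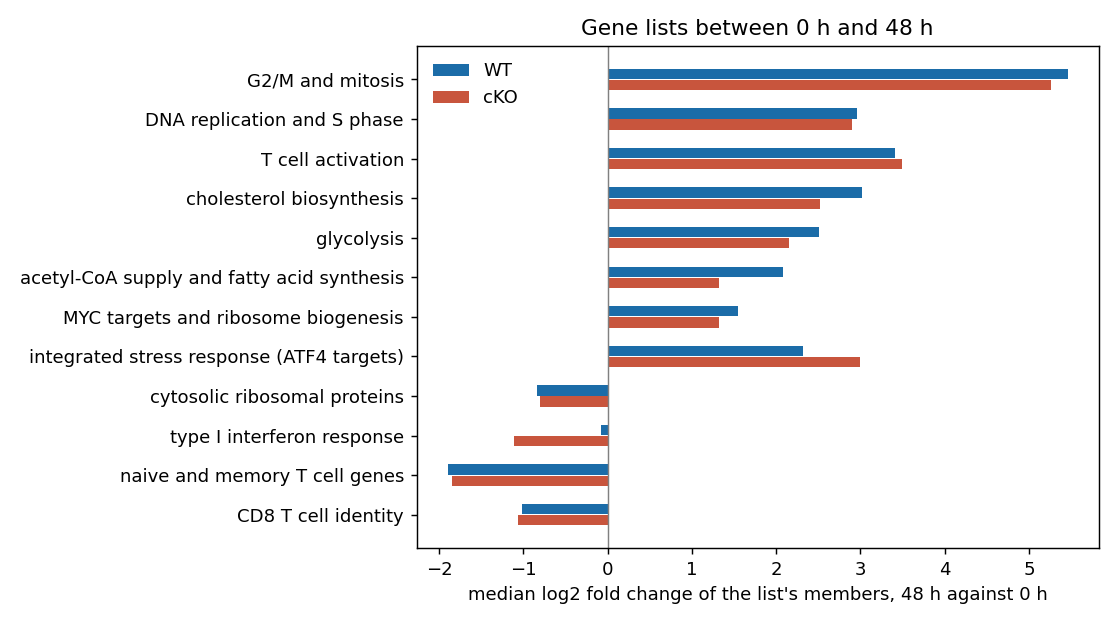
Median log2 fold change from 0 h to 48 h of 12 gene lists, in WT and in cKO, over the members tested. The G2/M list lies highest in both, at 5.46 and 5.26, and the cholesterol biosynthesis list lies at 3.02 in WT and 2.52 in cKO.

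The comparison of cKO with WT at 0 h asks what differed before the 48 h. Few differences passed the test, no more than the 2 genes that edgeR called at 0 h in the simulated data with no change there. Dclk2, a doublecortin-like kinase, was the 1 gene called, with 4.19 ± 0.442 CPM in WT and 13.5 ± 3.48 CPM in cKO, a log2 fold change of 1.68 ± 0.22 (edgeR adjusted p = 0.0211). No gene was called lower by edgeR, with 1163 genes at an unadjusted p under 0.05 in either direction. DESeq2 called 22 higher and 18 lower, and limma-voom 0 of either. None of the 16 genes reported in every comparison was called, and Gzmb at 4.45 ± 0.748 and 3.27 ± 0.845 CPM, Myc at 169.8 ± 42.2 and 177 ± 2.4 CPM and Cd8a at 1414 ± 72.6 and 1500 ± 37.7 CPM are examples. For Dclk2, leaving out both libraries labelled cKO replicate 1, a choice made after seeing the data, gave 1.83 (edgeR adjusted p = 0.000881). Leaving out both libraries of WT replicate 3 gave 1.67 (edgeR adjusted p = 0.296).

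With the groups as labelled, gene lists at 0 h held no called member. In the cholesterol biosynthesis list 0 of 20 members were called, also when adjusted over the list alone, and its median was -0.13 (camera adjusted p = 0.101). The type I interferon list had the largest shift past the camera test among immune response lists, with a median of 0.51, 0 of 36 members called and 0 adjusted over the list alone (camera adjusted p = 3.03e-10, and adjusted p = 0.491 with an estimated correlation). Its mean log2 level against the WT mean was -0.34, 0.33 and 0.00 in WT, -0.09 in the library labelled cKO replicate 1, and 0.4 and 1.22 in cKO replicates 2 and 3, and without cKO replicate 3 at 0 h its median was 0.15 (camera adjusted p = 0.132). Ifi44 and Oas1a, interferon-induced genes, had 1.52 ± 0.477 and 9.88 ± 1.54 CPM in WT and 5.9 ± 4.96 and 23 ± 15.7 CPM in cKO and were not called. The lists of tRNA modification enzymes, of aminoacyl-tRNA synthetases, of MYC targets, of S phase genes and of glycolysis were slightly higher in cKO, with medians of 0.08, 0.08, 0.07, 0.07 and 0.08 (camera adjusted p = 0.000246, 0.0176, 0.0081, 0.00432 and 0.0228). The lists of p53 targets, of effector genes and of activation genes were lower, with medians of -0.15, -0.23 and -0.14 (camera adjusted p = 0.00278, 0.0103 and 0.0496). Adjusted over the list alone, 1 member was higher in the MYC and glycolysis lists, 1 lower in the p53 and effector lists, and 0 were called in the other 4. With an estimated correlation the adjusted p of these 8 lists lay at or above 0.458. Without WT replicate 1 at 0 h camera no longer called the glycolysis, p53, effector and activation lists. The aminoacyl-tRNA synthetase list was lost without WT replicate 2 at 0 h and without cKO replicate 2 or 3 at 0 h, the S phase list without cKO replicate 2 at 0 h and with limma-voom, and the effector and activation lists without cKO replicate 3 at 0 h and with limma-voom. Without both libraries labelled cKO replicate 1, a choice made after seeing the data, the cholesterol biosynthesis median was -0.19 with 0 of 20 called and 3 lower adjusted over the list alone (camera adjusted p = 0.00567, and adjusted p = 0.594 with an estimated correlation). In that setting the type I interferon median was 0.76 with 1 of 36 higher and 23 adjusted over the list alone (camera adjusted p = 2e-23, and adjusted p = 0.363 with an estimated correlation).

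Some marker lists of other cell types also differed between the 0 h groups by camera with a preset correlation. B cell markers summed to 291, 233 and 358 CPM in WT and 235, 246 and 208 CPM in cKO, so WT replicate 2 lay among the cKO libraries. The median of the B cell list was -0.7, with 0 of 16 members called and 4 lower when adjusted over the list alone (camera adjusted p = 8.25e-07, and adjusted p = 0.458 with an estimated correlation). Pax5, the B cell transcription factor, had 19.2 ± 4.43 and 10.6 ± 0.64 CPM. The lists of NK and innate lymphoid cells and of CD4 and regulatory T cells were lower in cKO and the erythroid list higher (camera adjusted p = 0.00528, 0.00595 and 0.000734, and adjusted p = 0.458, 0.458 and 0.491 with an estimated correlation). Erythroid markers summed to 20, 119 and 15 CPM in WT and 64.6, 133 and 83.3 CPM in cKO, so 1 WT library lay among the cKO libraries. Camera no longer called the NK and CD4 lists without WT replicate 1 at 0 h, nor the erythroid and NK lists with a filter at 1 CPM.

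Single libraries moved the 0 h count. It was 3 higher without WT replicate 1 at 0 h and 2 higher and 5 lower without WT replicate 2 at 0 h. It was 4 higher without the library labelled cKO replicate 1 at 0 h, 2 higher and 1 lower without that library at 48 h, and 0 without WT replicate 3 at either time or without cKO replicate 2 or 3 at 0 h. Without both libraries labelled cKO replicate 1 edgeR called 12 higher and 7 lower, and without both of WT replicate 3 it called 0, with 694 at an unadjusted p under 0.05.

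The comparison of cKO with WT at 48 h bears on the title's topic of cholesterol biosynthesis through messenger RNA levels only. These counts hold no measure of tRNA modification, protein or cholesterol. By edgeR 9 of 20 cholesterol biosynthesis genes, 5 of 15 genes of acetyl-CoA supply and fatty acid synthesis and 9 of 20 glycolysis genes were lower in cKO. Of the naive and memory genes 9 of 30 were higher and 1 lower. Camera called these 4 lists with a preset correlation and none of them with an estimated correlation (adjusted p = 0.267 for each). Hmgcs1, the enzyme that makes HMG-CoA, had 635 ± 37.5 CPM in WT and 374 ± 116 CPM in cKO, Scd1, a stearoyl-CoA desaturase, had 98.9 ± 15.1 and 24.4 ± 13.2 CPM, and Gzmb had 3956 ± 466 and 2295 ± 429 CPM. In all, 384 genes were higher and 135 lower in cKO, 26 and 12 of them by at least 2-fold, and 2753 had an unadjusted p under 0.05 (edgeR). DESeq2, run on all 16352 genes of the deposited table, called 702 higher and 352 lower. The share of higher genes was 74 percent by edgeR, 66.6 percent by DESeq2 and 54.3 percent by limma-voom.

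In the cholesterol biosynthesis list 9 of 20 members fell and none rose by edgeR, and 17 fell when adjusted over the list alone. The list's median log2 fold change was -0.63 (camera adjusted p = 3.35e-17, and adjusted p = 0.267 with an estimated correlation, and fry adjusted p = 0.051). Acat2, which joins acetyl-CoA units, changed by -0.91 ± 0.16. Mvd, the mevalonate diphosphate decarboxylase, changed by -0.83 ± 0.16 and Fdps, the farnesyl diphosphate synthase, by -0.78 ± 0.16. Hmgcs1 changed by -0.76 ± 0.16 and Pmvk, the phosphomevalonate kinase, by -0.69 ± 0.13. The edgeR adjusted p of these 5 ran from 0.011 for Acat2 to 0.0187 for Hmgcs1. Sqle at -0.57 ± 0.21 (edgeR adjusted p = 0.133) and Srebf2, which encodes the transcription factor that drives these genes, at -0.26 ± 0.097 (edgeR adjusted p = 0.135) were not called. The mean log2 level of the list lay between -0.05 and 0.07 of the WT mean in the 3 WT libraries, at -0.24 in the library labelled cKO replicate 1, and at -0.9 and -0.73 in cKO replicates 2 and 3. Without both libraries of WT replicate 3 the median was -0.56 and no member was called, 16 being lower when adjusted over the list alone. In the list of sterol sensing and uptake 3 of 12 fell, Insig1 by 0.67 on the log2 scale (SE 0.15), Stard4, a sterol carrier, by 0.57 (SE 0.14) and Scarb1, a lipoprotein receptor, by 0.49 (SE 0.12), and Mylip, a ubiquitin ligase, rose by 0.73 ± 0.18. Adjusted over the list alone 1 rose and 5 fell (camera adjusted p = 0.0103, and adjusted p = 0.287 with an estimated correlation). In the list of sterol efflux and LXR genes Arl4c rose by 0.26 ± 0.063 and the other 9 of 10 were not called, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.31).

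**Figure D3:**
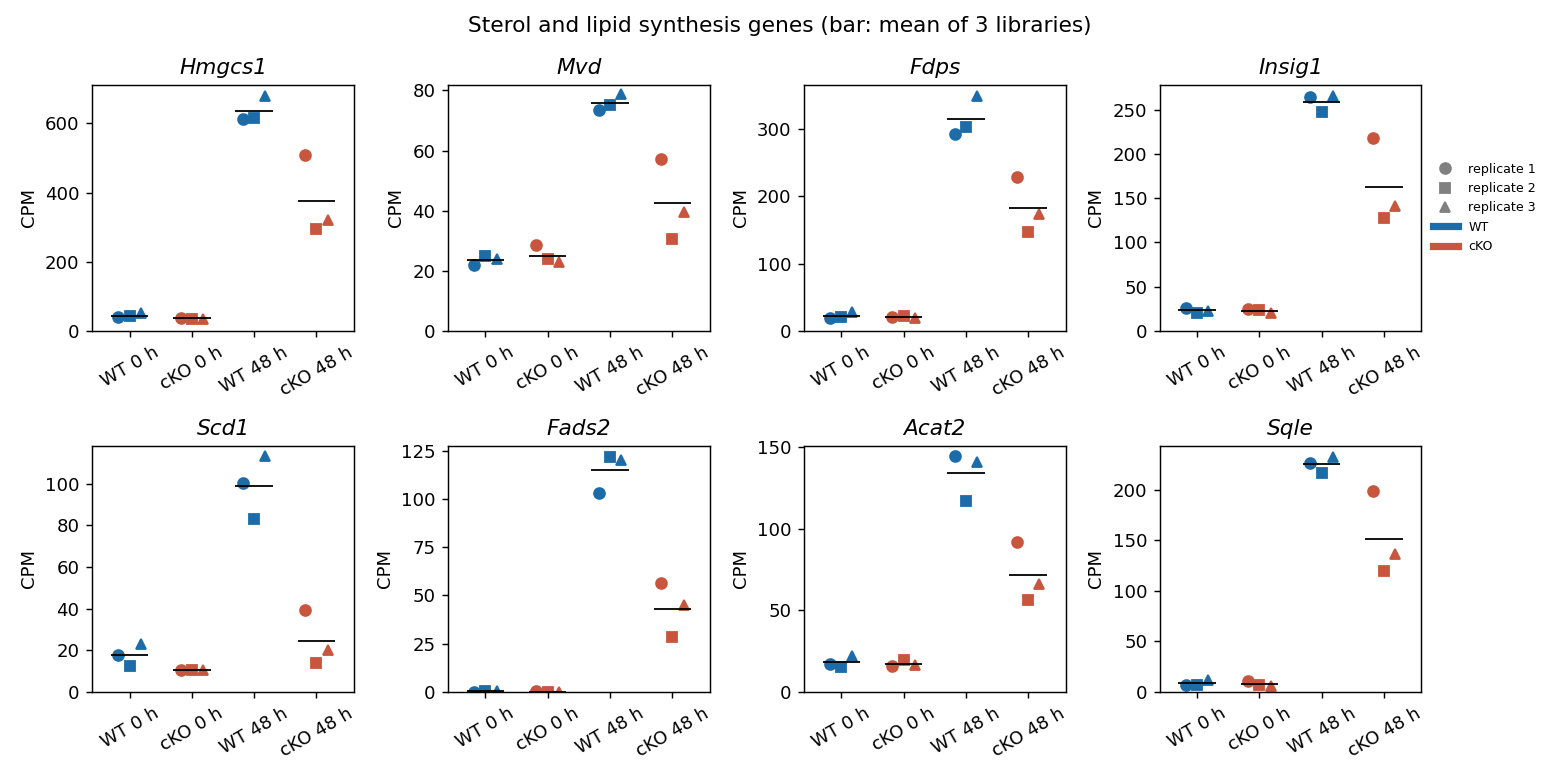
Levels in CPM of 8 sterol and fatty acid genes in each of the 12 libraries, with 1 point per library and a bar at each group mean. At 48 h Hmgcs1 averages 635 CPM in WT and 374 CPM in cKO and Scd1 98.9 and 24.4 CPM, and the library labelled cKO replicate 1 is the circle in the cKO groups.

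In the list of acetyl-CoA supply and fatty acid synthesis 5 of 15 fell and 8 did so when adjusted over the list alone, with a median of -0.31 (camera adjusted p = 8.51e-09, and adjusted p = 0.267 with an estimated correlation). Scd1 changed by -2.02 ± 0.29, Fads2, a fatty acid desaturase, by -1.42 ± 0.22, Scd2 by -0.99 ± 0.17 and Elovl6, which elongates fatty acids, by -0.89 ± 0.17, with edgeR adjusted p from 0.00405 to 0.0139. Acly, which makes cytosolic acetyl-CoA, had 608 ± 16.4 CPM in WT and 481 ± 75.3 CPM in cKO and was not called, at -0.34 ± 0.096 (edgeR adjusted p = 0.0632). DESeq2, limma-voom, upper-quartile scaling, the fit without a low-count filter and the fit with a replicate block called it.

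In the glycolysis list 9 of 20 fell, 15 adjusted over the list alone, with a median of -0.37 (camera adjusted p = 1.15e-13, and adjusted p = 0.267 with an estimated correlation). Tpi1 changed by -0.49 ± 0.091, Ldha, which makes lactate, by -0.43 ± 0.082, Pkm by -0.39 ± 0.081 and Pgk1 by -0.36 ± 0.072, with edgeR adjusted p from 0.0126 to 0.0185. The list's level was below that of each WT library in the 3 libraries labelled cKO, at -0.38 in the library labelled cKO replicate 1 and -0.59 and -0.19 in cKO replicates 2 and 3, against -0.09 to 0.08 in WT. Of 75 nuclear-encoded oxidative phosphorylation genes 4 fell, 5 adjusted over the list alone, among them Uqcrfs1 and Ndufs6 by 0.37 and 0.35 on the log2 scale (camera adjusted p = 6.68e-11, and adjusted p = 0.421 with an estimated correlation). In the unfolded protein response list 3 of 22 genes fell, 11 when adjusted over the list alone. They were Manf by 0.55, Pdia6 by 0.5 and Xbp1, a transcription factor of this response, by 0.38 on the log2 scale (camera adjusted p = 1.48e-05, and adjusted p = 0.287 with an estimated correlation).

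T cell state genes moved both ways at 48 h. In the naive and memory list 9 of 30 rose and 1 fell, 12 and 1 adjusted over the list alone (camera adjusted p = 3.16e-07, and adjusted p = 0.267 with an estimated correlation). S1pr1 rose by 0.82 ± 0.094, Klf3 by 0.67 ± 0.093, Dgka, which damps signalling by diacylglycerol, by 0.44 ± 0.063 and Ccr9 by 0.96 ± 0.18, with edgeR adjusted p from 0.00204 to 0.0129. In the effector list 2 of 32 rose and 2 fell, 3 and 4 adjusted over the list alone, its median of -0.01 and its mean of 0.02 differed in sign, and camera did not call it (adjusted p = 0.694). Gzmb changed by -0.79 ± 0.15 and Ifng by -1.05 ± 0.24, from 379.7 ± 61.4 to 183 ± 56.9 CPM. Xcl1, a chemokine that attracts dendritic cells, rose by 0.9 ± 0.12, from 112 ± 6.67 to 208 ± 23.8 CPM, and Klrd1, a lectin-like receptor chain, by 0.61 ± 0.14. Lag3 and Ctla4 changed by -0.81 ± 0.21 and -0.9 ± 0.24, and Il2rb by -0.4 ± 0.094. Itgae, the integrin CD103, rose by 1.17 ± 0.23 and Pou2af1, a transcriptional coactivator, by 1.03 ± 0.13. Prf1, Tnf, Il2, Il2ra, Cd69, Cd8a, Mki67 and Myc were not called, with log2 fold changes of 0.1 ± 0.11, -0.08 ± 0.22, -0.02 ± 0.18, -0.24 ± 0.13, 0.15 ± 0.24, 0.02 ± 0.06, 0.07 ± 0.13 and -0.26 ± 0.13.

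Among the genes that rose most at 48 h were Ttc28, from 4.28 ± 1.2 to 11.1 ± 3.36 CPM, and Acsbg1, an acyl-CoA synthetase, by 1.26 ± 0.27. Ccdc141 fell most, from 15.7 to 3.16 CPM, with Plaur, the urokinase receptor, by 1.16 and Tnip3 by 1.31 on the log2 scale.

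With the groups as labelled, growth and cell cycle lists were slightly lower, with no member called in any of them by edgeR, adjusted over the list alone or over the tested genes. The medians were -0.19 for MYC targets and ribosome biogenesis, -0.13 for translation factors, -0.12 for S phase and -0.09 for G2/M (camera adjusted p = 1.2e-07, 0.000858, 0.000626 and 0.0103). With an estimated correlation their adjusted p lay between 0.287 and 0.514. The activation list had a median of -0.18, with 1 member lower, 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0102, and adjusted p = 0.421 with an estimated correlation), a call lost without WT replicate 2 at 48 h or the library labelled cKO replicate 1 at 48 h. The type I interferon list had 0 of 36 called and a median of -0.46 (camera adjusted p = 0.00292, and adjusted p = 0.765 with an estimated correlation), a call lost without WT replicate 2 at 48 h (camera adjusted p = 0.168) or without the library labelled cKO replicate 1 at 48 h (camera adjusted p = 0.358). Camera called none of these lists: tRNA modification enzymes (0 of 38 called, median -0.09), aminoacyl-tRNA synthetases (0 of 23, median -0.02, mean 0.0005), ribosomal proteins (0 of 79, median -0.0025), inhibitory receptors (2 of 14 lower), p53 targets (0 of 27), BCL2 family (0 of 17), nutrient transporters (0 of 20), immediate early genes (1 of 24 lower) and CD8 identity (1 of 14 higher).

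Genes of the integrated stress response, the programme driven by the transcription factor ATF4, split the libraries labelled cKO. With the groups as labelled, 0 of 27 members were called, also when adjusted over the list alone, and the median was 0.5 (camera adjusted p = 0.00196, and adjusted p = 0.69 with an estimated correlation). The mean log2 level against the WT mean was -0.3, 0.2 and 0.1 in WT, -0.79 in the library labelled cKO replicate 1, and 1.09 and 1.19 in cKO replicates 2 and 3. Without both libraries labelled cKO replicate 1, a choice made after seeing the data, 22 of 27 members rose and none fell by edgeR, with a median of 0.85 (camera adjusted p = 4.28e-26, and adjusted p = 0.0231 with an estimated correlation). In that setting Atf5, a stress-induced transcription factor, rose by 1.96 (edgeR adjusted p = 3.8e-05). There Cth, a cysteine synthesis enzyme, rose by 2.38 (edgeR adjusted p = 9.65e-06), Ddit3 by 1.72 and Asns, the asparagine synthetase, by 1.99 (edgeR adjusted p = 0.000148 for both). With the groups as labelled the same genes had 1.49 ± 0.42, 1.87 ± 0.55, 1.26 ± 0.43 and 1.48 ± 0.55. The list's as-labelled call, at 0.00196, was lost without cKO replicate 2 at 48 h (camera adjusted p = 0.125). It was also lost without cKO replicate 3 at 48 h (camera adjusted p = 0.334). Both of these fits kept the libraries labelled cKO replicate 1.

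Few markers of other cells differed at 48 h. S100a9 and S100a8, abundant in neutrophils, were called, at 0 and 0.00885 CPM in WT and 1.45 ± 0.443 and 0.812 ± 0.267 CPM in cKO, and were the only members called of 24 myeloid markers, which summed to 92.8 to 102 CPM in WT and 99.4 to 117 CPM in cKO (camera adjusted p = 0.00282, and adjusted p = 0.514 with an estimated correlation). Pecam1, on the endothelial list, rose by 0.43 ± 0.069, and Izumo1r, on the CD4 and regulatory T cell list, by 0.86 ± 0.18. Camera called neither of these 2 lists (adjusted p = 0.403 and 0.924), and the median of the CD4 list, -0.17, and its mean, 0.03, differed in sign, as did those of the B cell list, -0.06 and 0.17. The lists of B cells, plasma cells, dendritic cells, NK cells, gamma delta T cells, erythroid cells and platelets had 0 called members by edgeR and were not called by camera.

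Leaving out both libraries labelled cKO replicate 1, a choice made after seeing the data, changed the counts of other lists at 48 h as well. By edgeR 17 of 20 cholesterol biosynthesis genes were then lower, 20 adjusted over the list alone, with a median of -0.81 (camera adjusted p = 7.09e-26, and adjusted p = 0.139 with an estimated correlation). In the fatty acid list 9 of 15 were lower, 10 adjusted over the list alone (camera adjusted p = 3.82e-13, and adjusted p = 0.0231 with an estimated correlation). Lower were also 12 of 20 glycolysis genes, 28 of 75 oxidative phosphorylation genes, 26 of 42 MYC targets and 7 of 50 S phase genes by edgeR, with none higher. Adjusted over the list alone the counts were 15, 39, 30 and 7. In the lists of the unfolded protein response, translation factors, G2/M and tRNA modification enzymes 13 of 22, 16 of 38, 9 of 44 and 7 of 38 were lower and 2, 3, 1 and 1 higher by edgeR. Adjusted over the list alone 14, 20, 9 and 8 were lower and 2, 4, 1 and 2 higher. In the lists of nutrient transporters, aminoacyl-tRNA synthetases and naive and memory genes 8 of 20, 7 of 23 and 12 of 30 were higher and 2, 5 and 1 lower by edgeR. Adjusted over the list alone 9, 9 and 13 were higher and 2, 7 and 1 lower.

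**Figure D4:**
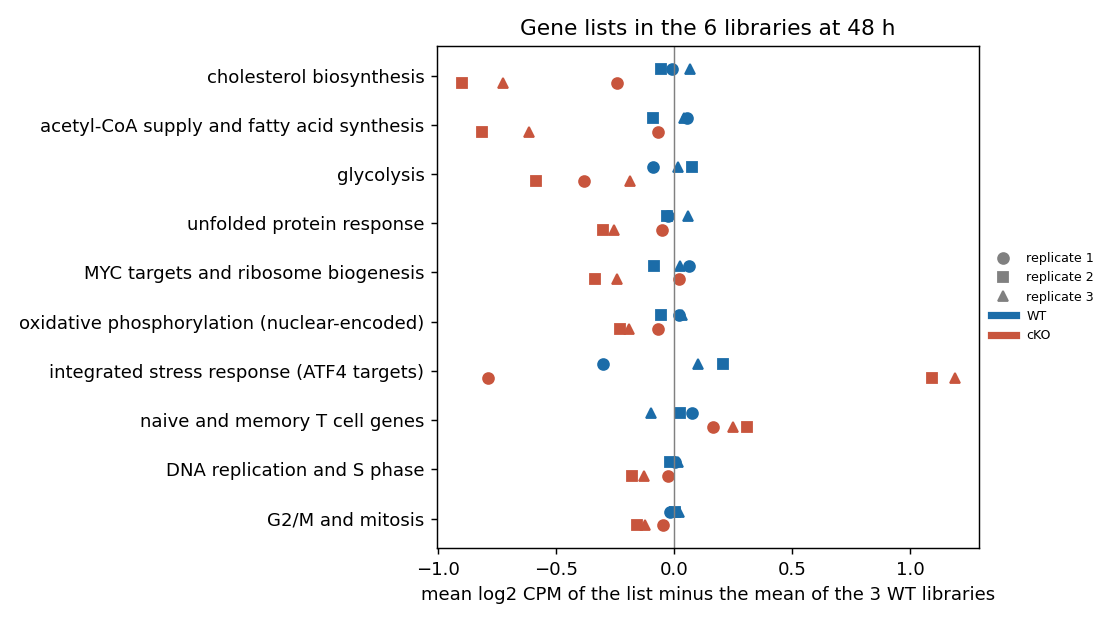
Mean log2 CPM of 10 gene lists in the 6 libraries at 48 h, each minus the mean of the 3 WT libraries. The cholesterol biosynthesis list lies at -0.9 and -0.73 in cKO replicates 2 and 3 and at -0.24 in the library labelled cKO replicate 1, and the integrated stress response list at 1.09, 1.19 and -0.79.

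The number of calls at 48 h depended on single libraries. Without the library labelled cKO replicate 1 at 48 h there were 1221 higher and 1069 lower. Without cKO replicate 2 at 48 h there were 70 and 8, and without cKO replicate 3 at 48 h 191 and 39. The counts were 247 and 48 without WT replicate 1 at 48 h, 276 and 60 without WT replicate 2 at 48 h, 52 and 7 without WT replicate 3 at 48 h, and 232 and 77 without cKO replicate 2 at 0 h. Of the 58 named genes called, 15 stayed called whichever library was left out: Baiap3, Dgka, Fads2, Klf3, Mturn, Pecam1, Pou2af1, S100a8, S100a9, S1pr1, Scd1, Scd2, Tlr12, Ttc28 and Xcl1, and Tpi1 was lost only without WT replicate 3 at 48 h. Without both libraries labelled cKO replicate 1, 1148 genes were higher and 1114 lower, and 514 of the 519 were called again in the same direction. Without both libraries of WT replicate 3 there were 17 and 1, each of these 18 among the 519, and the 519 kept their sign.

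The interaction asks whether the change from 0 h to 48 h differed between cKO and WT. It called 13 genes with a higher change in cKO and 1, Galk1, with a lower one, and 2073 had an unadjusted p under 0.05 (edgeR). Of the 13, 12 had a smaller drop in mean CPM in cKO than in WT, and Pou2af1 had a higher mean at 48 h than at 0 h in cKO. Pou2af1 went from 28.3 to 14.3 CPM in WT and from 23.6 to 29.2 CPM in cKO, an interaction of 1.3 ± 0.18. Kmt2a, a histone methyltransferase, went from 592 to 225 and from 468 to 354 CPM, an interaction of 0.99 ± 0.17. Gbp8 and Zbtb4 had interactions of 0.89 ± 0.15 and 0.86 ± 0.14, and S1pr1 and Klf3, of the naive and memory list, 0.83 ± 0.13 and 0.81 ± 0.13. Galk1, the galactokinase, rose from 19.2 to 163 CPM in WT and from 28.9 to 133 CPM in cKO, an interaction of -0.89 ± 0.15. The edgeR adjusted p of these named genes ran from 0.0301 to 0.0411. DESeq2 called 316 higher and 133 lower.

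With the groups as labelled, lists with a smaller or larger change in cKO held few called members. In the cholesterol biosynthesis list 0 of 20 were called and 6 were lower when adjusted over the list alone, with a median interaction of -0.48 (camera adjusted p = 1.37e-08, and adjusted p = 0.428 with an estimated correlation). In the glycolysis list 0 of 20 were called and 10 were lower adjusted over the list alone, with a median of -0.45, Hk2 at -1.18 ± 0.22 and Tpi1 at -0.69 ± 0.13, both with edgeR adjusted p = 0.0589 (camera adjusted p = 1.93e-13, and adjusted p = 0.345 with an estimated correlation). In the naive and memory list 2 of 30 were called, 7 adjusted over the list alone, with a median of 0.26 (camera adjusted p = 2.88e-06, and adjusted p = 0.345 with an estimated correlation). The type I interferon list had 0 of 36 called, 3 lower adjusted over the list alone, and a median of -1.02 (camera adjusted p = 1.9e-10, and adjusted p = 0.447 with an estimated correlation). Its camera calls between cKO and WT at 0 h and at 48 h were each lost without single libraries, as given above. With an estimated correlation camera called none of the 36 lists in the interaction.

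The interaction without both libraries labelled cKO replicate 1, a choice made after seeing the data, called more members of these lists. By edgeR 10 of 20 cholesterol biosynthesis genes were lower, 13 adjusted over the list alone, with a median of -0.58 (camera adjusted p = 5.08e-13, and adjusted p = 0.203 with an estimated correlation), among them Mvd (adjusted p = 0.00546), Pmvk (adjusted p = 0.00941) and Acat2 (adjusted p = 0.0138). In the glycolysis list 7 of 20 were lower, 12 adjusted over the list alone, with a median of -0.43 (camera adjusted p = 5.11e-09, and adjusted p = 0.288 with an estimated correlation), among them Tpi1 (edgeR adjusted p = 0.0173) and Hk2 (edgeR adjusted p = 0.0184). Lower were also 7 of 15 fatty acid genes, 17 of 42 MYC targets, 11 of 75 oxidative phosphorylation genes, 5 of 50 S phase genes, 2 of 44 G2/M genes and 5 of 36 interferon genes by edgeR. Adjusted over the list alone the counts were 7, 28, 21, 5, 7 and 19. Higher were 9 of 27 integrated stress response genes and 7 of 30 naive and memory genes by edgeR, or 14 and 10 adjusted over the list alone. In that setting, too, camera with an estimated correlation called none of these lists, the lowest adjusted p being 0.0957.

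Single libraries moved the interaction count as well. Higher and lower calls were 537 and 460 without the library labelled cKO replicate 1 at 48 h, 26 and 0 without WT replicate 1 at 48 h, and 17 and 5 without cKO replicate 3 at 48 h. They were 15 and 4 without WT replicate 1 at 0 h, 4 and 1 without WT replicate 2 at 0 h, 4 and 3 without the library labelled cKO replicate 1 at 0 h, 1 and 0 without cKO replicate 2 or 3 at 0 h, and 0 without WT replicate 3 at either time or without WT replicate 2 or cKO replicate 2 at 48 h. Without both libraries labelled cKO replicate 1 they were 448 and 425, and without both of WT replicate 3 edgeR called 0, with 1319 at an unadjusted p under 0.05.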

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

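The tests of explanations in this part, including the splits into other groups, were chosen after the results were seen, and the interaction itself was fixed before.

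The change from 0 h to 48 h differed between cKO and WT for 14 genes by the edgeR interaction test, which is what brought these results here. It was higher in cKO for 13 genes and lower for 1. The log2 differences were 1.299 for Pou2af1, 0.9928 for Kmt2a, 0.889 for Gbp8, 0.8562 for Zbtb4 and -0.8852 for Galk1. Over 100 splits of the libraries, the real one included, 6 called as many genes as the real 14, and the highest other split called 106. For the cholesterol biosynthesis list 21 of the 100 splits gave a median as far from 0 as the real -0.478, with 0.8376 as the highest other, and each of the 21 kept cKO replicates 2 and 3 at 48 h on the same side. The 5 other splits that called as many as the real one each kept the 48 h libraries parted by genotype, and 4 of them regrouped the 0 h libraries. The split with 106 calls set the WT libraries at 0 h with the cKO libraries at 48 h. It thus tested the sum of the genotype differences at 0 h and at 48 h, apart from sign. That makes it no measure of chance for the interaction. Another 4 splits also kept the 48 h libraries parted by genotype, with the 0 h libraries regrouped, and called 0, 1, 0 and 0 genes, so the calls depend on the grouping at both times. Of the 90 splits that mixed the genotypes at 48 h none called more than 12. The splits that reached the real values thus carried all or part of the 48 h difference, and neither count decides whether chance can be excluded.

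Lists whose change over time differed between cKO and WT by camera had these median log2 differences. Lower in cKO were cholesterol biosynthesis at -0.478, sterol sensing and uptake at -0.1726, acetyl-CoA supply and fatty acid synthesis at -0.2653, tRNA modification enzymes at -0.1743, aminoacyl-tRNA synthetases at -0.1043, the unfolded protein response at -0.2147, MYC targets and ribosome biogenesis at -0.2441, translation factors at -0.102 and glycolysis at -0.4452. Oxidative phosphorylation at -0.1792, S phase at -0.1822, G2/M at -0.1966, type I interferon at -1.023 and immediate early genes at -0.2008 were also lower. The interferon calls between cKO and WT at 0 h and at 48 h each depended on single libraries. Higher were naive and memory T cell genes at 0.2612, B cell markers at 0.4217 and myeloid markers at 1.093, and these 2 marker medians include genes near 0 counts and are no bound on the share of such cells. For the cytosolic aminoacyl-tRNA synthetases list, genotype by time interaction turned sign to 0.01053 without the library labelled cKO replicate 1 at 48 h and was -0.04152 without both libraries of that label, and camera called it in neither setting. With an estimated correlation camera called none of these lists, the lowest adjusted p being 0.345.

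Trmt61a stayed at the WT level in the 2 libraries labelled cKO replicate 1. A swap with a library labelled WT needs a WT library without the transcript, and the lowest WT level, 26.3 CPM, argues against it. A mixture with at least 0.5 of the cells deleted is argued against by the lower of the 2 ratios to the WT mean, 1.01. An undeleted animal under a cKO label remains open. The slope of this library's 48 h difference from WT on that of cKO replicates 2 and 3 averaged 0.089 and ran from 0.0276 to 0.155. Between WT libraries the slopes averaged 0.0831 in size, with the sign dropped, and reached 0.125. Because of the dropped sign, 0.089 and 0.0831 are not like measures. Between cKO replicates 2 and 3 the mean slope was 0.384. The slopes above 0 leave open that the library labelled cKO replicate 1 differs from WT in part. So does its cholesterol biosynthesis level at 48 h, -0.24 against -0.05 to 0.07 in WT. Its integrated stress response level at 48 h, given above, lay below the WT libraries, whereas cKO replicates 2 and 3 lay above them. Its departure from WT was thus not in the direction of cKO replicates 2 and 3 for each list.

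The cholesterol biosynthesis list was lower in cKO at 48 h. WT replicate 3, the libraries without Y-linked counts, as the whole cause is argued against by the median of -0.564 without both of them, with 20 of 20 members below 0. These members come from the same libraries and are not independent. In that setting no member was called by edgeR, and the fry adjusted p of the list was 0.15. A weaker response shared alike with the cell cycle lists is argued against by the share of the WT list median that the cKO list median lacked. This share was 1.96 percent for S phase and 3.57 percent for G2/M against 16.6 percent for cholesterol biosynthesis. Median interactions of single members were -0.1822 and -0.1966 against -0.478. A response weaker across growth and metabolic genes stays open. The share was 36.5 percent for fatty acid synthesis, 14.1 percent for glycolysis, 15 percent for MYC targets and -2.44 percent for activation genes. Without both libraries labelled cKO replicate 1 it was 21.7 percent for MYC targets and 19.8 percent for cholesterol biosynthesis. It was then 3.21 percent for S phase and 2.8 percent for G2/M. On the first principal component of the 12 libraries, WT lay between 96.6 and 101 at 48 h. There cKO replicates 2 and 3 lay at 81.5 and 87.8 and the library labelled cKO replicate 1 at 88.5. The library that kept Trmt61a thus lay beside the other cKO libraries on this component. Loss of Trmt61a in the cells, or a difference between the animals other than that, stays open and was not tested apart.

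The 10 splits of 6 libraries are too few for a share under 0.05, so only the real and the highest other values are given, with the number of splits as large as the real one. At 0 h, 5 splits called as many genes as the real 1, the highest other being 30, and 6 had a cholesterol biosynthesis median as far from 0 as -0.131, the highest other being 0.1983. The split with 30 calls set WT replicates 1 and 2 and cKO replicate 3 against the rest, which points to a structure of the samples other than genotype. At 48 h the numbers were 1 split for 519 genes, the highest other being 4, and 1 for the median of -0.6279, the highest other being 0.4856. For 48 h against 0 h in WT they were 1 for 9351 genes, the highest other being 0, and 1 for 3.018, the highest other being 0.8517. In cKO they were 1 for 9004 genes, the highest other being 0, and 1 for 2.516, the highest other being 1.019.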

How the results depend on the processing

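Leaving out both libraries of a replicate number and leaving out the 4 libraries of cKO replicate 1 and WT replicate 3 were tests chosen after the results were seen. Of 437 pairs of a named gene and a comparison, 354 kept their side of the threshold under every alternative run for them. A change of direction was counted only where the gene was called with or without the alternative. Of 86 pairs of a list other than cholesterol biosynthesis and a comparison, 61 kept their direction and side of the threshold. The comparisons over time held best. Whichever library was left out, 158 of 158 named genes called stayed called in WT and 157 of 159 in cKO. For cKO against WT it was 0 of 1 at 0 h and 15 of 58 at 48 h, and for the interaction 0 of 8. The cholesterol biosynthesis list at 48 h stayed between -0.8078 and -0.467 in every setting. For the values below that moved, the cause was not tested. With DESeq2, genes higher and lower in cKO were 22 and 18 at 0 h, 702 and 352 at 48 h, and 316 and 133 in the interaction. Of the calls, 55 percent were higher at 0 h, 66.6 percent at 48 h and 70.4 percent in the interaction, against 100, 74 and 92.9 percent by edgeR. Without a filter on low counts they were 4 and 2 at 0 h, 207 lower at 48 h, and 97 and 25 in the interaction. With only the 6 libraries compared, 0 genes were higher at 0 h, and 141 were higher and 85 lower at 48 h. With limma-voom 0 genes were higher at 0 h, 302 were lower at 48 h (54.3 percent of its calls higher), 2 were lower in the interaction, and Trmt61a at 48 h was called at -3.376. Without all 4 libraries of cKO replicate 1 and WT replicate 3 there were 6 and 3 at 0 h, 706 and 725 at 48 h, and 82 and 90 in the interaction, with Trmt61a at -4.408 at 0 h and -5.284 at 48 h.

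Without single libraries or both of a number, the ranges for genes higher and lower were 0 to 12 and 0 to 7 at 0 h, 17 to 1221 and 1 to 1114 at 48 h, and 0 to 537 and 0 to 460 in the interaction. Trmt61a ranged from -4.375 to -0.8941 at 0 h and from -5.215 to -0.7986 at 48 h, and cholesterol biosynthesis at 0 h from -0.2175 to 0.06128. For Trmt61a, 48 h vs 0 h in cKO gave -3.302 without the library labelled cKO replicate 1 at 48 h and 3.471 without that at 0 h, as that library holds the transcript at the WT level and the other libraries labelled cKO hold little of it. In the cytosolic aminoacyl-tRNA synthetases list, genotype by time interaction medians ran from -0.1523 without cKO replicate 3 at 48 h to 0.01053 without the library labelled cKO replicate 1 at 48 h. Leaving out both libraries of a number at 48 h gave 180 and 44 for WT 1, 154 and 21 for WT 2, 23 and 5 for cKO 2, and 146 and 49 for cKO 3.

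The labels do not pair the libraries. Libraries of the same genotype and number at 0 h and 48 h correlated at 0.0708, 0.0973 and 0.151 in WT and at 0.0521, 0.0628 and 0.0338 in cKO, each higher than with the other numbers. WT replicate 3 also lacked Y-linked counts at both times, and the library labelled cKO replicate 1 kept Trmt61a at both times. These are hints from the data that a number marks a shared source, not the design. The correlations are low, and the libraries were not paired in the fit reported above. With a replicate block by the number in the titles, 1 gene was higher and 0 lower at 0 h, and 418 and 198 at 48 h. With a block by genotype and number, there were 4544 and 4703 in WT over time, 4429 and 4418 in cKO, and 16 and 21 in the interaction. Depth limits genes of low level, where a count of 100 has an error of 10 percent.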

Other observations

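The pathway sets described here were fixed before the data were examined by taking the deposited annotations, and the pathways named were chosen after their values were seen. At 48 h the proteasome, the complex that degrades ubiquitin-tagged proteins, had 2 of 45 genes lower in cKO by edgeR, also when adjusted over the set alone, with a median log2 fold change of -0.19 (camera adjusted p = 9.6e-09, and adjusted p = 0.854 with an estimated correlation). The pentose phosphate pathway, which makes NADPH and ribose, had 3 of 23 genes lower, and 9 lower and 1 higher adjusted over the set alone (camera adjusted p = 0.000123, and adjusted p = 0.854 with an estimated correlation). The steroid biosynthesis pathway had 4 of 19 lower, and 10 lower and 2 higher adjusted over the set alone, with a median of -0.47 (camera adjusted p = 0.000501, and adjusted p = 0.854 with an estimated correlation). From 0 h to 48 h in WT, lists not described above rose too. Nutrient transporters rose in 18 of 20 cases with 1 lower, fatty acid synthesis genes in 12 of 15 with 3 lower and oxidative phosphorylation genes in 58 of 75 with 5 lower (camera adjusted p = 0.00013, 0.00195 and 0.000222, and adjusted p = 0.0941, 0.336 and 0.475 with an estimated correlation).

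On the first principal component of the 48 h libraries, which held 38 percent of the variance, WT replicates 1 to 3 lay at -23.7, -9.64 and -27.5, the library labelled cKO replicate 1 at -8.98, and cKO replicates 2 and 3 at 37.9 and 31.8. On that of the 0 h libraries, with 29.7 percent, WT replicates 1 to 3 lay at -6.84, -0.512 and -38.4, the library labelled cKO replicate 1 at -17.3, and cKO replicates 2 and 3 at 25.5 and 37.5. The chi-square per gene between the library labelled cKO replicate 1 and cKO replicates 2 and 3 at 48 h was 52.9 and 47.9, against 13 between replicates 2 and 3 and 13.6 to 16 between WT libraries. At 0 h the chi-square per gene did not set that library apart, with 15.1 and 38 against cKO replicates 2 and 3, 22.9 between replicates 2 and 3, and 21.5 to 37.6 between WT libraries.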
